A study of Mus musculus with 4 samples.

How the data were processed

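The series holds 4 arrays of total RNA from sorted mouse cells, 2 of the Flk-1 positive, Etv2-Venus negative population and 2 of the Flk-1 positive, Etv2-Venus positive population. RNA was extracted with a Qiagen kit and labelled with biotin by an Affymetrix 3' in vitro transcription kit, per the labels' protocols. The deposited values are log2 expression values per probe set, made by the authors with RMA in R 2.8.0, per the submitters' processing notes. The log base is taken from the values, which run from 2.16 to 14.93. RMA corrects background, normalizes between arrays and summarises the probes of a probe set. The sorted values of the 4 arrays lay within 0.0564 of each other's mean, as normalization to a common distribution leaves them. Such values are relative, so a shift common to all genes is removed, and large differences are compressed near background and near saturation. Detection calls and scanner files were not used here.

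Groups and array numbers were taken from the sample titles. Gene symbols came from the platform's annotation, updated through Entrez identifiers with the RefSeq genes of GRCm38.p6, which was used for names only. Of the probe sets on the array, 64 were controls, 34958 had 1 symbol, 932 had several and 9160 were not listed in the annotation table used. Of those with 1 symbol, 34754 were matched by Entrez identifier and 0 symbols changed. Genes were represented by the probe set with 1 symbol that had the highest mean over the 4 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Of 41 named genes with several probe sets of mean 5 or more, 1 had probe sets of opposite sign. Arap3, Pcdh8, Amhr2, Tmem204, Fermt3, Aurkb and Wnt5b were read on probe sets of a type that can also bind related transcripts.

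The populations were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the only term, 2 residual degrees of freedom per gene and 2.68 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 18193 genes, with a threshold of 0.05. For 4 genes the deposited values, compared without rounding, were equal within both groups. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 22 lists, and again with the correlation estimated per list and with fry. Of 461 listed genes, 444 were measured. The remaining 17 had no match among the 18193 genes and were not used here. They included T of the streak list and Ccnb1 of the cell cycle list. Members were also adjusted over the list alone.

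The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Etv2, Kdr and Pdgfra, then per direction the 15 largest differences among genes past the threshold, with arrays apart and a mean of at least 6 in the higher group. As fewer than 10 passed, it fell back to the 10 with the largest moderated t, and it added up to 4 members with the smallest p of each list. It named 105 genes. Genes outside the rule are marked as chosen after their values were seen.

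The alternatives were every probe set in place of 1 per gene, the mean over a gene's probe sets, only genes with a mean of at least 6, a mean-variance trend with robust estimation, quantile normalization run again, arrays centred on their medians, the array number as a block, and leaving out each array. Combining the block with the trend was added after seeing the data. The limma step was tested on simulated data for 18193 genes of this comparison, with 50 genes changed at each of 4 sizes. With the moderated variances it called 10% of genes at a log2 size of 0.5, 96% at 1, 98% at 1.5 and 100% at 2, with 11 false calls. With each gene's own residual variance it called 0%, 24%, 52% and 72%, with 3 false calls. The moderated variances are more alike between genes than their own variances, so the shares called with them may be too high. In the real fit 109 genes were at least 2-fold higher and 77 lower, and 0 were called. In a simulation of the list test a list moved by 0.5 was called with the preset correlation (camera adjusted p = 1.92e-36). It was not called with an estimated correlation (camera adjusted p = 0.107), and 0 of 21 unmoved lists were called with the preset. The simulated genes varied independently, so the simulation does not show how often unmoved lists of correlated genes would be called. Figures were drawn with matplotlib 3.10.9.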

Results

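Gene expression was compared between 2 populations of Flk-1 positive cells derived from mouse embryonic stem cells of the TT2 line. The cells were heterozygous for a Venus fluorescent reporter knocked into Etv2 and were differentiated on OP9, a mouse bone marrow stromal line that supports mesoderm and blood formation. The sample labels give day 5. Flk-1, the VEGF receptor encoded by Kdr, marks mesoderm that can form blood and vessels, and Etv2 is an ETS family transcription factor of the blood and endothelial lineages. Sorting on Venus separated an Etv2-Venus negative from an Etv2-Venus positive population, with 2 arrays of each, numbered 1 and 2. The array medians were 5.50 and 5.52 log2 units in the negative and 5.46 and 5.49 in the positive population. The number of arrays limits the precision. The labels do not state that the arrays came from separate cultures, so the p-values of genes measure only the spread between these arrays, which may be technical. The list test with the preset correlation compares members with the other genes. Its p-values rest on the number of genes and do not measure a spread between arrays. Differences are given as Etv2-Venus positive minus negative on the log2 scale, with the standard error (SE) of the fit.

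The genes of the sort were read first as a check of the labels. Etv2 measured 12.03 and 11.87 on the negative arrays and 12.64 and 12.41 on the positive arrays, a difference of 0.57 (SE 0.13, 1.49-fold, n = 2 arrays per group). Both positive arrays thus lay above both negative arrays, and Etv2 signal was high in the Venus negative cells as well. The sources used here do not place the probe set relative to the Venus insertion, so it is open whether this signal reads both alleles. Kdr, on which both populations had been selected, measured 12.60 ± 0.12 in the negative and 12.73 ± 0.12 in the positive cells (SD, n = 2 each), with a difference of 0.13 (SE 0.12). Pdgfra, a receptor of early mesoderm, measured 10.11 and 9.41 on the negative arrays and 8.55 and 7.67 on the positive arrays, a difference of -1.65 (SE 0.38). Over all genes the limma adjusted p was 0.185 for Etv2, 0.777 for Kdr and 0.195 for Pdgfra. Adjusted over the list alone, Etv2 and Pdgfra passed, each at 0.0124, and Kdr did not, at 0.317.

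**Figure D1:**
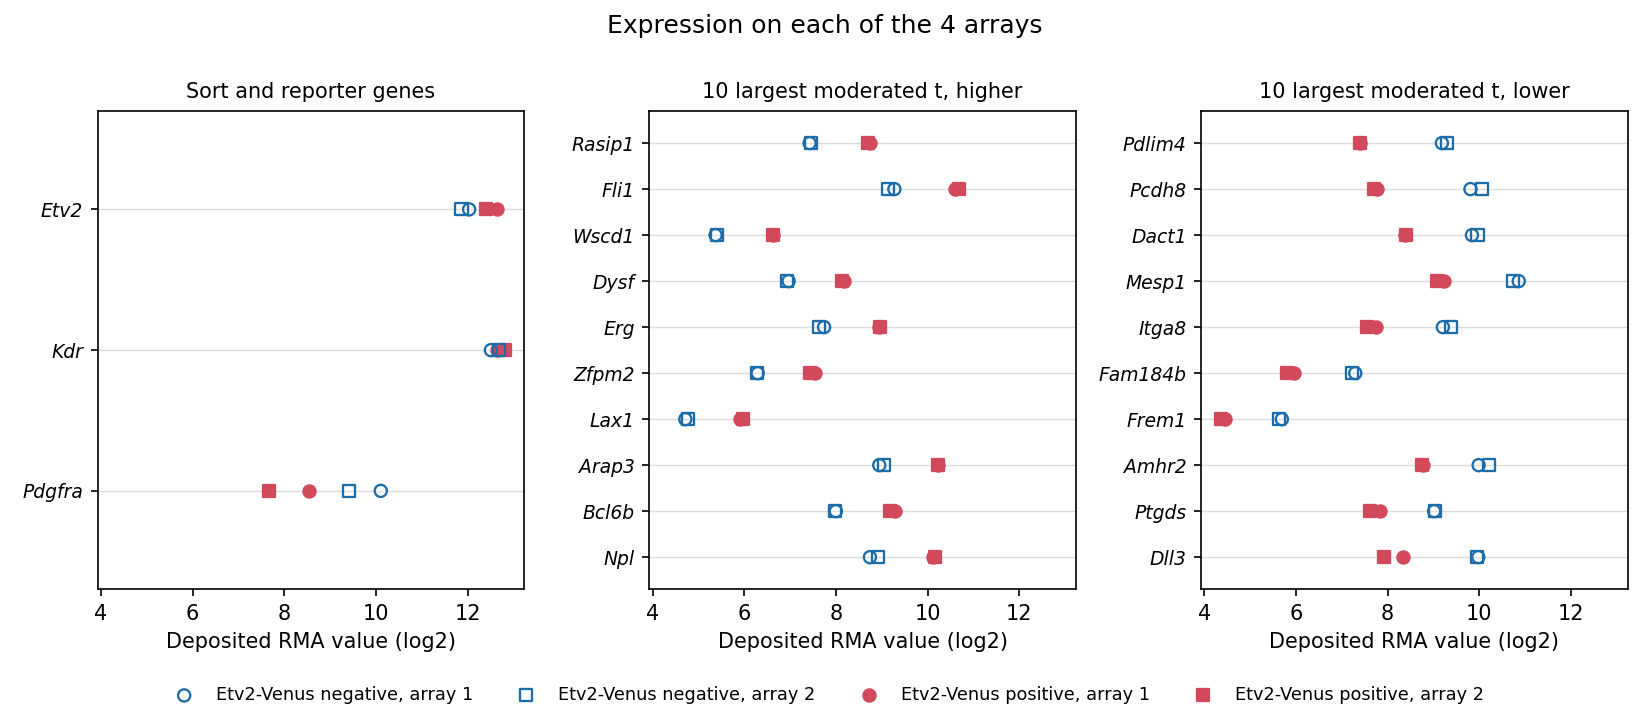
Deposited RMA values (log2, horizontal axis) of Etv2, Kdr and Pdgfra and of the 10 genes with the largest moderated t in each direction; open blue symbols are the Etv2-Venus negative arrays, filled red symbols the positive arrays, circles number 1 and squares number 2. For Fli1 the positive arrays lie at 10.61 and 10.68 and the negative arrays at 9.27 and 9.14, while for Kdr the arrays of the 2 populations overlap.

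The comparison of the sorted populations addresses which genes differ within Flk-1 positive mesoderm according to Etv2 reporter activity. Fli1 and Erg, ETS factors of blood and endothelium, measured 9.20 ± 0.10 and 7.68 ± 0.08 in the negative cells and 10.64 ± 0.05 and 8.95 ± 0.00 in the positive cells (SD, n = 2), differences of 1.44 (SE 0.10) and 1.27 (SE 0.09). Rasip1, a Ras-interacting protein needed for vessel lumens, differed by 1.29 (SE 0.09, 2.44-fold), and Bcl6b, a transcriptional repressor expressed in endothelium, by 1.24 (SE 0.09). Wscd1, Dysf, Zfpm2, Lax1, Arap3 and Npl were the other members of the 10 genes with the largest moderated t for higher expression, with differences from 1.20 to 1.31. In the opposite direction stood Pcdh8, a protocadherin of the presomitic mesoderm, at -2.20 (SE 0.12), Pdlim4 at -1.83 (SE 0.09), the Notch ligand Dll3 at -1.83 (SE 0.16) and Mesp1, a transcription factor of nascent mesoderm, at -1.64 (SE 0.11). Itga8, Dact1, Fam184b, Amhr2, Ptgds and Frem1 completed the 10 genes for lower expression, with differences from -1.65 to -1.26. All of these genes had arrays that did not overlap between the populations, which the choice by moderated t favours. Lax1, at 4.74 and 5.94 in the negative and positive cells, and Frem1, at 5.66 and 4.40, were dim, so their sizes are uncertain.

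None of the 18193 genes passed an adjusted p of 0.05 in limma, so 0 genes were called higher and 0 lower, and the 20 genes above were taken by rank and not by a call. The smallest adjusted p was 0.0670, shared by 66 genes. At an adjusted p under 0.10 there were 172 genes higher and 62 lower in the positive cells. At an unadjusted p under 0.05 there were 2131 genes, 1287 higher and 844 lower, where chance gives 910 for independent arrays, which the shared array numbers leave open. Differences of at least 2-fold, taken without a test, were seen for 109 genes in the higher direction, all with arrays apart, and for 77 in the lower direction, 74 with arrays apart. Over all genes the arrays of the populations did not overlap for 39.5%, and chance gives 33.3% for 2 arrays against 2. The count of calls differed between settings. With a mean-variance trend and robust estimation limma called 81 genes higher and 31 lower, and among the genes with a mean of at least 6 log2 units it called 66 and 13.

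**Figure D2:**
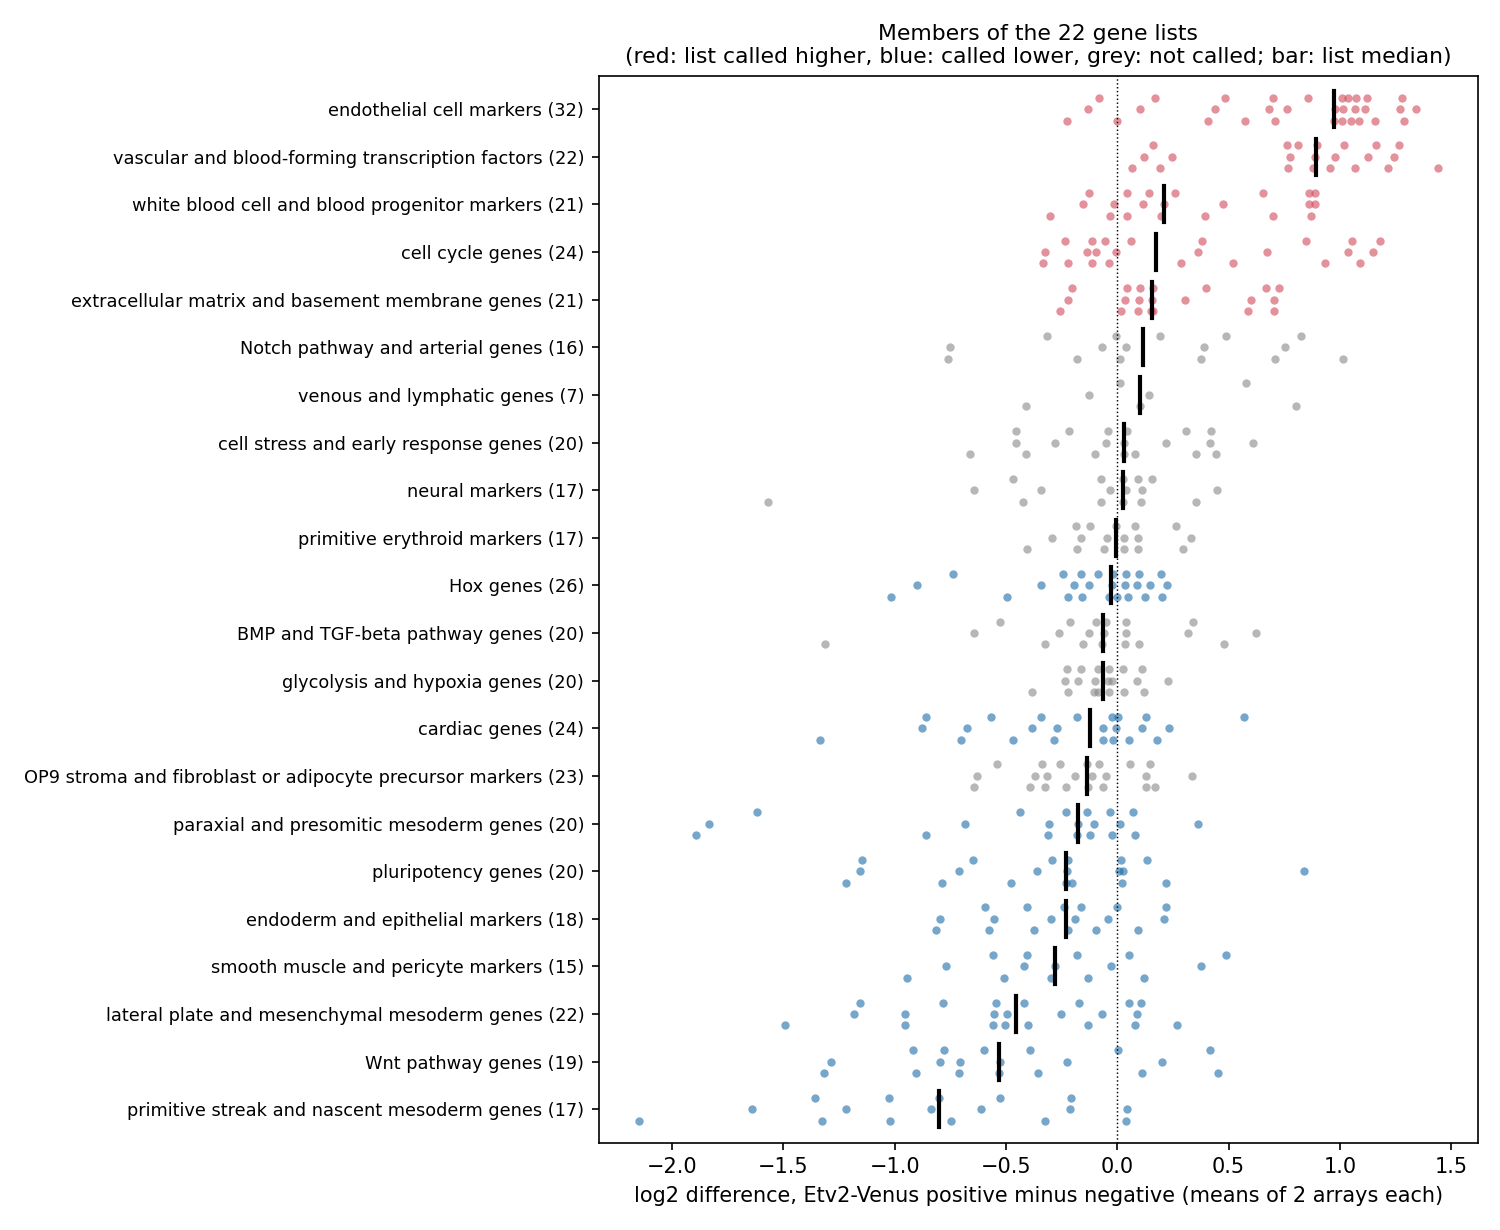
Log2 differences (Etv2-Venus positive minus negative, horizontal axis) of the measured members of the 22 gene lists; each point is a gene, the black bar is the list's median, the number measured stands in brackets, and colour shows the call of the list test with the preset correlation. Medians run from 0.97 for endothelial cell markers to -0.80 for primitive streak and nascent mesoderm genes.

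Of the 22 gene lists tested against the other genes with camera, 5 were called higher in the positive cells, 9 lower and 8 were not called. None of the 14 calls held with an estimated correlation between genes, and those p-values are given beside each list. In the self-test that setting also missed a list moved by 0.5 whose genes varied independently. A call lost with it therefore does not show that correlation between genes produced the call. In no list did a member pass when adjusted over all genes, so the counts of members below are adjusted over the list alone.

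Endothelial and blood-forming genes were the lists furthest towards the positive cells. Endothelial cell markers had a median difference of 0.97, and 25 of 32 measured members passed as higher while 0 passed as lower (camera adjusted p = 5.89e-21; adjusted p = 0.146 with an estimated correlation). Of the 32 members, 4 had a difference below 0. The arrays were apart in the higher direction for 26 and in the lower direction for 3. Flt4, a VEGF receptor, measured 9.33 ± 0.05 and 10.60 ± 0.14 (SD, n = 2), Mmrn2 rose by 1.28 (SE 0.11) and Tmem204 by 1.11 (SE 0.09). The 7 members that did not pass lay between -0.23 for Cd93 and 0.68 for Vwf, both chosen after their values were seen. Vascular and blood-forming transcription factors had a median of 0.89, with 17 of 22 members higher and 0 lower (adjusted p = 2.06e-20; adjusted p = 0.146 with an estimated correlation). Besides Fli1, Erg and Bcl6b, Hhex, a homeobox factor of blood and endothelial precursors, rose by 1.07 (SE 0.09), from 10.58 ± 0.00 to 11.65 ± 0.01 (SD, n = 2). White blood cell and blood progenitor markers were called higher as a list, with a median of 0.21, 7 of 21 members higher and 14 not passing (adjusted p = 0.000115; adjusted p = 0.215 with an estimated correlation). Plek and Fermt3, which act in platelets and leukocytes, both rose by 0.89 (SE 0.09 and 0.10), Itga2b, an integrin of early blood progenitors, by 0.70 (SE 0.11) and Gfi1, a repressor of emerging blood cells, by 0.86 (SE 0.16). Compared within the arrays numbered 1 and within those numbered 2, the medians were 0.99 and 0.93 for endothelial markers, 0.88 and 0.91 for the transcription factors and 0.14 and 0.26 for the white blood cell list.

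Primitive erythroid markers had a median of -0.01 and 0 of 17 members passed (camera adjusted p = 0.627), and the embryonic globins Hba-x and Hbb-bh1 measured 5.64 ± 0.13 and 5.15 ± 0.11 in the positive cells (SD, n = 2), near the array median. Notch pathway and arterial genes were not called as a list (adjusted p = 0.151), and their members went both ways. Acvrl1, Dll4 and Hey2, known from arterial endothelium, rose by 0.82 (SE 0.13), 0.75 (SE 0.17) and 0.71 (SE 0.14), and the ligand Jag1 fell by 0.75 (SE 0.13). Acvrl1 and Dll4 were dim, at 5.72 and 5.66 in the positive cells, so the size of their differences is uncertain. Of the 7 venous and lymphatic genes 1, Nrp2, rose, by 0.58 (SE 0.12), and the list was not called (adjusted p = 0.663), but it was called higher with every probe set (0.000447). Fry, which tests a list against no change and not against the other genes, gave 0.0436. Aplnr measured 13.52 ± 0.09 and 13.66 ± 0.17 and did not pass.

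The lists of mesoderm genes were called lower in the positive cells with the preset correlation, although many members did not pass. Primitive streak and nascent mesoderm genes had the lowest median, -0.80, with 5 of 17 members lower and 0 higher (camera adjusted p = 3.32e-09; adjusted p = 0.275 with an estimated correlation). Mesp1 fell from 10.79 ± 0.09 to 9.15 ± 0.11 (SD, n = 2), Lhx1 by 1.33 (SE 0.12), Eomes by 1.03 (SE 0.14) and Lefty2, an antagonist of Nodal signalling, was at -2.15 (SE 0.33), with a mean of 4.25 in the positive cells, below the array median, so that its size is uncertain. Snai1, chosen after its value was seen, was the fifth member that fell, by 1.22 (SE 0.21). Lateral plate and mesenchymal mesoderm genes had a median of -0.46, with 10 of 22 lower (adjusted p = 6.98e-08; adjusted p = 0.180 with an estimated correlation), among them Bmp4 at -0.78 (SE 0.09), Hand2 at -0.96 (SE 0.14), Foxf1 at -1.49 (SE 0.24) and Msx2 at -1.16 (SE 0.21). Paraxial and presomitic mesoderm genes had a median of -0.18, with 4 of 20 lower (adjusted p = 2.00e-05; adjusted p = 0.215 with an estimated correlation). These were Dll1 at -1.89 (SE 0.19), Dll3, Tbx6, a T-box factor of presomitic mesoderm, at -1.62 (SE 0.20) and Mesp2 at -0.86 (SE 0.13), with the size for Tbx6 uncertain at a mean of 4.51 in the positive cells. Within the arrays numbered 1 and 2 the medians were -0.91 and -0.69 for the streak list, -0.45 and -0.45 for the lateral plate list and -0.24 and -0.23 for the paraxial list.

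Cardiac genes had a median of -0.12, with 6 of 24 lower and 0 higher (camera adjusted p = 0.000520; adjusted p = 0.242 with an estimated correlation). Actc1, a sarcomeric actin, fell by 1.33 (SE 0.24), Isl1 by 0.88 (SE 0.17), Gata4 by 0.70 (SE 0.15) and Myl7 by 0.57 (SE 0.10). Smooth muscle and pericyte markers had a median of -0.28, and 1 of 15 fell, Rgs5, by 0.94 (SE 0.13; list adjusted p = 0.0418; adjusted p = 0.397 with an estimated correlation). That call was lost without array 1 or array 2 of the negative cells (adjusted p = 0.0579 and 0.0652) and without array 2 of the positive cells (0.0680). It was also lost with the mean over each gene's probe sets (0.0651) and after quantile normalization run again (0.0547).

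Wnt pathway genes had a median of -0.53, with 9 of 19 members lower (camera adjusted p = 6.03e-07; adjusted p = 0.306 with an estimated correlation). The ligands Wnt5b and Wnt5a fell by 1.29 (SE 0.18) and 0.78 (SE 0.12), the receptor Fzd1 by 0.79 (SE 0.11) and the secreted antagonist Sfrp1 by 1.32 (SE 0.22), so ligands, a receptor and an inhibitor were lower together. The receptor Fzd10, chosen after its value was seen, was the only member that rose, by 0.45 (SE 0.12). BMP and TGF-beta pathway genes were not called (adjusted p = 0.320) and split, with Tgfbr2 and Id4 higher by 0.62 (SE 0.10) and 0.48 (SE 0.11), and Bmper and Fst lower at -0.64 (SE 0.09) and -1.31 (SE 0.26). The Hox list had a median of -0.03 and was called lower (adjusted p = 0.0418; adjusted p = 0.306 with an estimated correlation), with 2 of 26 members lower, Hoxb1 at -1.02 (SE 0.15) and Meis2, a Hox cofactor and not a Hox gene, at -0.90 (SE 0.12). This call was lost without array 2 of the negative cells (adjusted p = 0.188), without array 1 of the positive cells (0.411) and after quantile normalization run again (0.0871).

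Pluripotency genes had a median of -0.23, with 1 of 20 lower, Sall4, at -0.79 (SE 0.13; list adjusted p = 0.000749; adjusted p = 0.306 with an estimated correlation). Tbx3 and Lin28a differed by -0.65 (SE 0.15) and -0.36 (SE 0.11) and Dppa4 by 0.84 (SE 0.20), and these 3 did not pass. Endoderm and epithelial markers had a median of -0.23, with 3 of 18 lower (adjusted p = 0.000520; adjusted p = 0.397 with an estimated correlation). The keratins Krt18 and Krt8 fell by 0.81 (SE 0.10) and 0.80 (SE 0.16), and Epcam fell by 0.58 (SE 0.10), although its probe sets did not all share that sign. Neural markers were not called (adjusted p = 0.337), their median of 0.02 and mean of -0.13 had opposite signs, and Otx2, at -1.57 (SE 0.34), did not pass.

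Cell cycle genes were higher as a list (median 0.17; camera adjusted p = 0.00244; adjusted p = 0.507 with an estimated correlation), with 9 of 24 members higher and 1 lower. The members that rose act late in the cycle. Aurka and Aurkb, mitotic kinases, rose by 1.04 (SE 0.10) and 1.18 (SE 0.16), Cdk1, which drives entry into mitosis, from 10.83 ± 0.18 to 11.92 ± 0.08 (SD, n = 2) and Mki67 by 0.85 (SE 0.12). Mcm6, a subunit of the replicative helicase chosen after its value was seen, was the member that fell, by 0.33 (SE 0.09). Within the arrays numbered 1 and 2 the list medians were 0.15 and 0.24. Extracellular matrix and basement membrane genes were also higher as a list (median 0.16; adjusted p = 0.00207; adjusted p = 0.242 with an estimated correlation), with 3 of 21 members higher, the basement membrane components Nid1, by 0.67 (SE 0.10), and Col4a1, by 0.59 (SE 0.11), and the elastic fibre protein Emilin1, by 0.73 (SE 0.10). Cell stress and early response genes were not called (adjusted p = 0.663; median 0.03 and mean 0.01, while the test pointed lower), with Atf3 and Myc higher by 0.61 (SE 0.10) and 0.42 (SE 0.10) and Egr1, Fos and, chosen after its value was seen, Gadd45b at -0.66 (SE 0.10), -0.46 (SE 0.09) and -0.46 (SE 0.11).

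**Figure D3:**
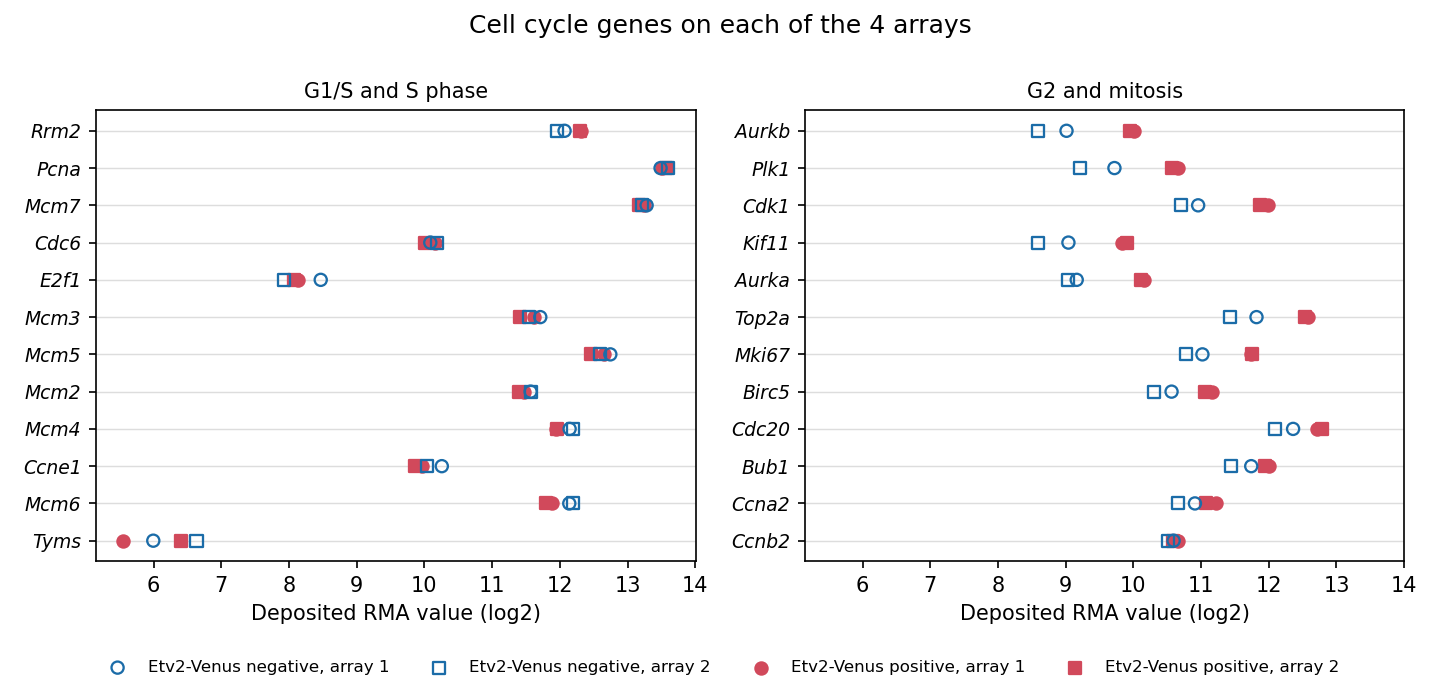
Deposited RMA values (log2, horizontal axis) of the 24 cell cycle genes, with 12 that act at G1/S and in S phase on the left and 12 that act in G2 and mitosis on the right; open blue symbols are the Etv2-Venus negative arrays, filled red symbols the positive arrays, circles number 1 and squares number 2. The median difference is -0.11 on the left and 0.89 on the right.

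Markers of the OP9 feeder, fibroblasts and adipocyte precursors were followed because such cells share the culture. Between the populations this list had a median of -0.14, 0 of 23 members passed and the list was not called (camera adjusted p = 0.106), and glycolysis and hypoxia genes were not called either (median -0.06, 0 of 20 members, adjusted p = 0.181). Both lists were called lower without array 2 of the negative cells (adjusted p = 0.00239 for stroma, 0.0112 for glycolysis) and without array 1 of the positive cells (0.000269 and 0.0222). Their direction turned to higher, uncalled, without array 2 of the positive cells for stroma (0.639) and without array 1 of the negative cells for glycolysis (0.914). The stroma list was also called with the arrays centred on their medians (0.0336). Within each population the stroma list was higher on the array numbered 1, by a median of 0.42 in the negative and 0.50 in the positive cells. The streak list was higher on the same arrays, by 0.39 and 0.19, the pluripotency list by 0.22 and 0.14 and the cell cycle list by 0.20 and 0.07, of which 0.20 exceeds that list's median difference of 0.17 between the populations. The 3' minus 5' signal of Tfrc, a control for RNA quality, was 1.46 and 0.85 on the negative arrays and 1.91 and 1.21 on the positive arrays, and that of Pcx was 1.06 and 0.85 against 0.92 and 0.58. For Actb it was 0.41, 0.40, 0.47 and 0.51 and for Gapdh -0.03, -0.04, 0.00 and 0.00, on probe sets close to the top of the scale.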

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

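The look at probe sets without a gene name, and the test of their direction, were chosen only after the gene results were seen. Among the probe sets that the annotation table used here does not list, 55 differed at least 2-fold between the populations with arrays that did not overlap, 6 higher and 49 lower in the Etv2-Venus positive cells. They are reported because they carry signal outside the comparison of named genes. Of these probe sets 10.9% were higher, against 59.6% of the genes with the same size of difference and arrays apart (Fisher exact p = 5.08e-11). Several probe sets can read the same transcript, so they are not independent and this p is too small. No explanation for the direction was tested.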

How the results depend on the processing

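The replicate block combined with a variance trend and robust estimation was chosen only after the results were seen. Limma called 0 genes in each direction with every probe set, the mean over probe sets, quantile normalization run again, arrays centred on their medians, the replicate block and each array left out. Among genes with a mean of at least 6 it called 66 higher and 13 lower, 41 and 12 of them at least 2-fold, where fewer genes were tested. With variance trend and robust estimation it called 81 and 31, 49 and 19 at least 2-fold, and 68 of the genes were shared with the former. The array number as a block with the trend gave 616 and 361, 106 and 68 at least 2-fold. The cause was not tested for these last 2 settings. With 1 array left out, the lone array is assumed to vary like those of the other population.

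None of the 14 list calls held with the correlation estimated per list. The adjusted p was 0.146 for endothelial markers and for vascular and blood-forming transcription factors, 0.215 for white blood cell and for paraxial genes, 0.180 for lateral plate, 0.242 for cardiac and for matrix, 0.275 for streak, 0.306 for pluripotency, Wnt and Hox, 0.397 for smooth muscle and for endoderm and 0.507 for cell cycle genes. The setting replaces a fixed correlation by an estimate from 2 residual degrees of freedom. Its p-values are also taken on these 2 degrees of freedom, where the preset takes them from the number of genes. With the estimated correlation the self-test, whose genes varied independently, also missed a list moved by 0.5. The estimate was below the preset 0.01 for vascular and blood-forming (0.0067), white blood cell (-0.028), lateral plate (-0.035), Hox (-0.027) and matrix (-0.028) genes. A higher correlation thus does not account for the loss of those calls. For the other called lists the estimate was above 0.01, up to 0.32 for cell cycle genes. Fry tests another question, a list against no change and not against the other genes. It passed 4 of the 14 called lists and not cardiac, streak, Wnt, Hox and matrix genes (0.124 each), paraxial (0.0699), cell cycle (0.126), smooth muscle (0.286), pluripotency and endoderm genes (0.293 each). It also passed venous and lymphatic genes (0.0436), which camera called with every probe set (0.000447). The smooth muscle call was lost with the mean over probe sets (0.0651) and quantile normalization (0.0547), and ranged from 0.0274 to 0.0680 with an array left out. The Hox call was lost with quantile normalization (0.0871) and in the replicate block with or without the trend (0.0565), and ranged from 0.00156 to 0.411 with an array left out. The stroma list was called with centred arrays (0.0336) and in the replicate block with or without the trend (0.0103), and ranged from 0.000269 to 0.914 with an array left out, and glycolysis genes from 0.0112 to 0.914. These ranges hold both directions, since stroma turned higher without array 2 of the positive cells (0.639) and glycolysis without array 1 of the negative cells (0.914). For all of these lists the cause was not tested. The variance trend left the p-value of every list unchanged, with the block and without it. The replicate block with the trend is therefore no separate test of the Hox and stroma lists, and its values repeat those of the block.

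Of the 105 named genes, Lyve1 changed sign, with the mean over probe sets (0.19, against -0.13). Among named genes, 25 passed the threshold with the filter on the mean, 33 with the trend and 77 in the block with the trend, and 0 with the other settings. The array numbers were seen in the data as a structure, since the differences between numbers 1 and 2 correlated at 0.543 between the populations, but the labels do not state that they pair the arrays. Arrays of the same number in different populations were more alike (r = 0.9941 and 0.9943, with 395 and 388 probe sets 2-fold apart) than arrays of the same population (0.9918 and 0.9910, with 781 and 856). Of the 18193 genes, 10179 had a mean of at least 6 log2 units. That level is a choice, since background was not measured here. RMA compresses differences of dim genes, so those of the globins and other genes below it are less certain in size.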

Other observations

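The tests of the array numbers, of the phases of the cell cycle and of the splits below were chosen only after the results were seen. Genes described here, apart from Cxcl12, lie outside the naming rule and were chosen after their values were seen, and none passed an adjusted p of 0.05 over all genes. Gimap4, Gimap8 and Gimap9 stood at 1.15 (SE 0.21), 1.22 (SE 0.18) and 1.06 (SE 0.25; n = 2 arrays per group), and Gimap1, of the endothelial list, at 0.48 (SE 0.09). Gimap9 was dim, at 4.90 in the negative and 5.96 in the positive cells, so its size is uncertain. Gimap8 was dim in the negative cells, at 5.37. Gimap4 was read on a probe set of a type that can also bind related transcripts. No list of the Gimap family was tested.

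On the other side, Pcdh19, a protocadherin, was at -2.22 (SE 0.22) and Frzb, a secreted Wnt antagonist, at -1.70 (SE 0.23). Aldh1a2, which makes retinoic acid, was at -1.27 (SE 0.18), and Crabp1 and Crabp2, which bind it, were at -1.52 (SE 0.26) and -1.11 (SE 0.19). The ligand Efna3 and the receptors Epha1 and Epha4 were at -1.33 (SE 0.25), -1.29 (SE 0.38) and -1.10 (SE 0.10), and Cfc1, a Nodal co-receptor, at -1.37 (SE 0.15). No list of these genes was tested, and the ephrin Efnb2 stood at 0.19 (SE 0.10).

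Genes of mitosis were higher in the Etv2-Venus positive cells while those of S phase were not. The 12 cell cycle members that act in G2 and mitosis had a median difference of 0.89 (0.74 within number 1 and 1.03 within number 2), and all 12 were above 0. The 12 that act at G1/S and in S phase had a median of -0.11, and 1 of them was above 0. A larger share of dividing cells would raise both sets, and stroma RNA diluting the negative cells would lower both there, and the S phase median of -0.11 with an upper quartile of -0.05 argues against either as the whole cause. The permutation p of 0.000170 between the sets measures the same difference that prompted the question and is no separate support. A longer passage through G2 and mitosis is a hypothesis for the pattern and was not tested.

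Stroma and streak genes were higher on the arrays numbered 1 of both populations. The stroma list's median difference between numbers lay at percentile 100 of 10000 random lists in both populations, which measures the same shift that prompted the question and is no separate support, and 16 of 23 members were higher on number 1 in both. On arrays 1 and 2 of the negative and then of the positive cells Lpl measured 10.36, 9.16, 10.39 and 8.92, Bgn 9.72, 8.66, 9.50 and 8.49, and Col1a2 10.02, 8.41, 9.79 and 7.96. Cd44 moved less, at 8.92, 8.58, 8.82 and 8.58, and Cxcl12 went the other way, at 8.46, 8.57, 7.79 and 7.98. RNA of OP9 stroma is a candidate source for these markers, although the Flk-1 gate would remove cells without Flk-1. The lists were fixed beforehand, and 0 of the 23 genes belong to another list. That overlap does not show the markers to be particular to stroma. Stroma RNA is argued against for the streak genes, whose linear excess on number 1 was larger in the negative than in the positive cells. The median ratio was 2.63 over 10 of 17 streak genes, against 1.01 over 9 of 23 stroma genes (permutation p = 0.000758). These genes were kept for a mean of at least 6 and for being higher on number 1 in both populations. Each excess compares 1 array with 1 array, and the permutation treats genes that vary together as independent, so this p is too small. RNA quality stays open. Between the numbers the 3' minus 5' signal differed by 0.655 for Tfrc and 0.274 for Pcx, while Actb and Gapdh were near saturation. Between the populations, positive minus negative, it differed by 0.405 for Tfrc and -0.200 for Pcx.

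The 4 arrays allow 3 splits into equal groups, splits too few for a share under 0.05. The real split gave 2131 genes at an unadjusted p under 0.05, as many being reached by 1 split, and the highest other gave 1863, the split by array number. That split follows a structure of the arrays other than their population. Malat1, a nuclear RNA chosen after its values were seen, measured 10.12 and 13.08 on the negative and 9.08 and 12.84 on the positive arrays. It was read on 1 of its 7 probe sets, of a type that can also bind related transcripts.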
